A study of Mus musculus and Rattus norvegicus with 35 samples.

How the data were processed

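The series measured RNA of mouse tissues, hippocampus and hippocampal fractions and of rat CA1 layers and cultured neurons, in 35 samples. RNA was extracted with TRIZOL and made into Illumina libraries, rRNA-depleted except for 1 oligo(dT)-selected brain library. A long-read sample of P30 hippocampus has no column in the tables used here and is not analysed here. Groups were taken from the labels before the data were examined. The 14-week brain replicate 1 is the poly(A)-selected library and was kept out of the tissue fits, which therefore use 15 libraries.

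The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.6 and Cufflinks 2.2.1 with the builds mm9 and rn5; the circRNA caller is not given in the sources used here. Gene values are TPM as deposited by the authors (24601 mouse and 22409 rat genes). The circRNA values are RPM as deposited, computed by the authors from reads over back-splice junctions, for 28482 mouse and 18075 rat circRNAs; what the denominator counts is not stated in the sources used here. In every library each value was a whole multiple of the smallest step (100% of values within a tolerance of 0.1), so whole reads were recovered by division, and their totals equalled those of the deposited circRNA lists for 99.6% of mouse and 100% of rat circRNAs. The mouse list held 28026 of the circRNAs and 456 were in the table alone. Listed circRNAs had the classes MEA (23461 mouse, 13141 rat) and CBR (4565 and 4934), which were not used here. Hosts are the deposited symbols, 5991 in mouse, of which 5914 are in the gene table, and 4745 in rat, of which 4713 are; 1678 mouse and 1526 rat circRNAs have no host symbol. A circRNA is named by its host and, where needed, its coordinates.

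Depth set the precision. A single read was worth 0.448 to 2.14 RPM in mouse and 0.763 to 1.05 in rat, and totals ran from 1287 to 30723 RPM in the mouse libraries other than the poly(A) library and from 7915 to 25907 in rat. For fits on circRNAs the pseudocount was 1.18 (tissues), 0.578 (hippocampus) and 0.837 (cultures), and a circRNA had to be above 0 in at least 3, 2 and 2 libraries. Genes had a pseudocount of 1 TPM and had to reach 1 TPM in as many libraries.

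The planned test was limma 3.58.1 in R 4.3.3 on log2 of value plus pseudocount, with eBayes and a trend, two-sided, Benjamini-Hochberg adjustment and a threshold of 0.05. The design named edgeR should the tables hold whole counts; they hold RPM, so limma was kept and edgeR 4.0.16 (quasi-likelihood on recovered reads) became an alternative. Tissue fits had a mean per tissue and an age term (9 residual degrees of freedom), hippocampus fits a mean per stage over 8 libraries (4) and culture fits a mean per treatment (2). Ratios to host subtract log2 host TPM plus 1. Fixed lists (20 lists, 429 genes) were tested by camera with a preset correlation of 0.01 where at least 5 members were tested, in the gene table for P30 and bicuculline and by host in the circRNA table, over all lists of a comparison. Members were also counted after adjustment over the list alone. Summed abundance and number of circRNAs were tested by exact permutation, synaptic hosts by the Fisher exact test over genes at 1 TPM or more, and by 10000 random lists drawn from 20 abundance bins. In single-library pairs no test was made; a ratio of reads has an exact 95% interval scaled by the value of a read, and each list's median was placed among 10000 matched random lists. A group at 0 was given a floor of 3 reads over the group, which yields the "at least" folds. These divide the arithmetic mean of the other group by that floor. They can therefore exceed the limma difference, which compares means of log2 values.

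Named circRNAs and genes follow a rule written before the data were examined. It takes the 6 largest differences in each direction among those past the threshold, with a mean in the higher group of at least 10 pseudocounts (genes 5 TPM) and the groups apart, and the 3 smallest p in each direction where none passes. It adds up to 3 members of each list with the smallest p, the circRNA with the highest mean of each of 18 fixed hosts (among them Rims2, Rims1, Homer1, Tulp4, Rmst, Dlgap1, Dlgap3, Rtn4, Hipk3, Mapk4, Klhl2, Zfp609, Gria2, Grm5, Erc2, Pclo and Cdr1), and the 5 highest and 5 lowest of each pair at 10 pseudocounts or 10 TPM. Gene models without a name are left out of the text, and items of the fixed hosts and lists that are withheld are not reported here.

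The planned circRNA fits were tested on simulated data at the observed depth. Apart from the changes put in, each circRNA had the same mean in all libraries, so real tissue and stage differences were absent. In tissues 8555 and in cultures 5281 simulated circRNAs passed the filter, against 5594 and 4120 in the data. The rates therefore describe such data and need not hold for the real libraries. The planned fits found 9.78% of 4-fold and 17.0% of 8-fold changes in the tissue comparison, and none of 82 and 1.16% in P30 against E18. In the cultures they found 3.75% and 20.0%, and 11.5% of unchanged circRNAs were also called. The residual variance of circRNAs with few reads was near 0, so a floor of 20 reads over the libraries of the fit was added after the results were seen. With it, 59.3% and 94.1% (tissues), 57.4% and 84.4% (stages) and 73.1% and 92.6% (cultures) of such changes were found, with 1.23%, 0.568% and 0% of unchanged circRNAs called. Ratios to host gave 49.4% and 94.0%, 33.0% and 75.5%, and 58.0% and 93.9%. Gene fits gave 90.0% and 99.0% (stages) and 72.0% and 85.0% (cultures). Of 200 unmoved simulated lists 1% fell outside the central 95% of random lists, and a moved list reached percentile 100.

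Alternatives tried were other pseudocounts and filters, libraries scaled to equal medians or equal circRNA totals, edgeR, no trend, no age term, 20-week libraries alone, the replicate number as a block, each library left out in turn and an estimated list correlation. Added after the data were seen were floors of 10, 20 and 50 reads, leaving out the P10 and P30 second libraries, the satellite-repeat models or the 14-week heart, liver and lung libraries, length-matched lists, and a permutation of circRNA totals within blocks. Gene lengths came from GENCODE vM21 on GRCm38 and served for length only. Figures were drawn with matplotlib 3.10.9 under python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.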

Results

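The series compared circular RNAs (circRNAs) and genes across mouse tissues, hippocampal development, neuronal compartments and rat cultures, in 34 RNA libraries with deposited values. Of these, 28 came from C57BL/6 mice and 6 from Sprague Dawley rats. Brain, heart, liver, lung and testis had 3 libraries each, 1 at 14 weeks and 2 at 20 weeks. A poly(A)-selected library was paired with the rRNA-depleted 14-week brain library. Hippocampus had 2 libraries each at E18, P1, P10 and P30. Synaptosomes, their homogenate, CA1 neuropil and CA1 somata had 1 mouse library each, and rat CA1 neuropil and somata had 1 each. Rat hippocampal neurons at DIV 28 received 40 µM bicuculline for 12 h or water, with 2 libraries each. The mouse libraries other than the poly(A) library held 1231 to 43523 circRNA reads (median 15927), recovered from the deposited values. They had 816 to 10713 circRNAs above 0 and 11728 to 15605 genes at 1 TPM or more. Rat libraries held 8879 to 24727 circRNA reads, 4105 to 8509 circRNAs and 13007 to 13971 genes at that level. P-values of limma, edgeR and the permutation tests measure the spread between libraries, because the labels do not say whether replicates are separate animals. The Fisher exact test compares genes with genes, and camera compares list members with the other genes or circRNAs. The chi-square tests set replicate libraries against counting error.

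The tissue comparison asked whether brain holds more circRNA than heart, liver, lung and testis. CircRNAs are made by back-splicing of exons and have no free ends, so they resist exonucleases and can build up in cells that do not divide. Their summed abundance was 27626 ± 2822 (mean ± SD, n=3) in brain and 4827 ± 4147 (n=12) in the other tissues. The geometric means, which the log2 scale of the test compares, differed 7.36-fold. The exact permutation test on log2 totals gave p = 0.0022, the smallest that 455 splits of 3 and 12 libraries can give. The geometric means of the 20-week libraries alone differed 8.47-fold (exact permutation, n=2 against 8, p = 0.0222, the smallest of 45 splits). Those of the 14-week libraries, with 1 brain, differed 5.55-fold. Liver was lowest at 1420 ± 154, followed by heart at 3617 ± 365, lung at 4254 ± 284 and testis at 10016 ± 5820. The testis spread came from the 14-week library, whose total of 16727 was 2.51 times the 20-week mean. Brain libraries also held more kinds of circRNA, 6432 ± 916 against 2155 ± 1744, although 14-week testis reached 7102. The geometric means of these numbers differed 3.65-fold (exact permutation, n=3 against 12, p = 0.00659). The number above 0 depends on depth. Brain libraries held 14068 to 21432 circRNA reads, liver libraries 1231 to 2120 and 14-week testis 23286. Restricted to circRNAs with a mean of at least 10 pseudocounts, the mean numbers were 59.3 and 47.5. Their geometric means differed only 1.27-fold (exact permutation, p = 0.0505). That set is small and nearly all detected in brain, so it says little about the wider repertoire.

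**Figure D1:**
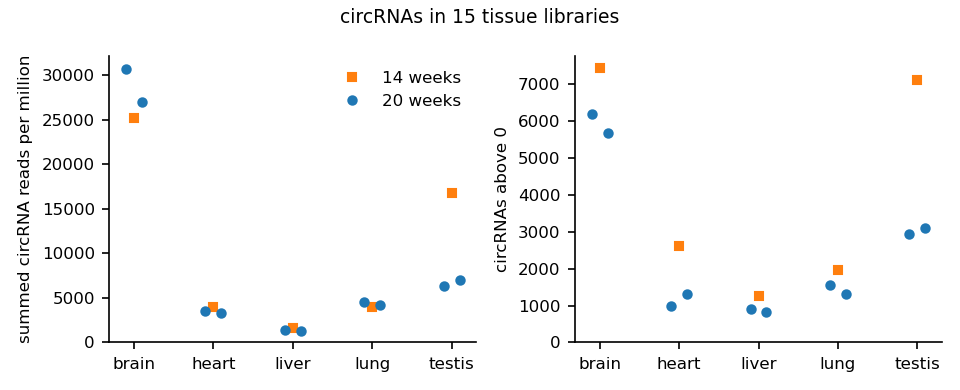
Summed circRNA abundance (deposited RPM) in each library of the 5 mouse tissues, by age. Every brain library lies above every library of heart, liver and lung, and 14-week testis comes closest.

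Synaptic genes were then asked about as sources of brain circRNA, because long, neuron-specific genes of the active zone and the postsynaptic density offer many exons for back-splicing. The presynaptic and postsynaptic lists held 83 genes that were expressed in brain. Of these, 45 (54.2%) hosted a circRNA seen in a majority of the 3 brain libraries, not necessarily in all. Among other expressed genes 2126 of 15355 did (13.8%, Fisher exact test, odds ratio 7.37, 95% interval 4.67 to 11.7, p = 7.88e-18). Presynaptic genes (22 of 41, odds ratio 7.14) and postsynaptic genes (23 of 42, odds ratio 7.46) contributed alike. Random lists of genes matched on expression held a median of 18 hosts, with 95% of lists between 11 and 26, and none of 10000 reached 45. Synaptic genes are also long, with a median length of 121386 bp against 23740 bp for other genes. Lists matched on expression and length, a comparison chosen after the first result was seen, held a median of 38 hosts (30 to 46), which placed the synaptic list at percentile 95.8. Length and expression together thus accounted for most of the excess.

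Individual circRNAs were compared between brain and the mean of the 4 other tissues by limma with an age term. The choices behind this fit were made before the data were examined, and gave 2666 circRNAs of 1468 host genes higher in brain and 150 lower, of 5594 tested. Of these 2816 circRNAs, 2185 had fewer than 20 reads over all 15 libraries. A floor of 20 reads, chosen after those results were seen, left 842 circRNAs, of which 596 from 437 host genes were higher and 66 from 53 host genes were lower. In the planned fit the counts were 1545 and 28 without 20-week brain replicate 1, 1696 and 28 without replicate 2, and 1678 and 25 without the 14-week brain library. Its lower count was 93 without either 20-week liver library, 59 and 56 without 20-week testis replicates 1 and 2, and 54 without 14-week testis. The values that follow use the floor. The median difference was 2.06 log2 units, so most of the shift was the larger circRNA total of brain. Scaling the libraries to equal medians cut the median to 0.55 and left 289 higher and 101 lower (74.1% of calls higher, against 90.0%), and equal totals left 219 and 86 (71.8%). With edgeR on recovered reads the counts were 630 and 2, so nearly all lower calls were made by limma alone. Leaving out 20-week brain replicate 1 reduced the higher count to 385. The lower count was 21 without 14-week testis, 28 and 29 without 20-week testis replicates 2 and 1, and 33 without the 14-week brain library. These sets have fewer reads, so 635, 745, 753 and 627 circRNAs reached the floor in the same order. Against single tissues with all circRNAs tested and no floor, limma counted 2122 higher and 54 lower against heart, 2374 and 29 against liver, and 2139 and 82 against lung. Against testis it counted 1817 and 563, the most lower calls of the 4 tissues. The 14-week testis library held 23286 circRNA reads, against 1231 to 5232 in the heart, liver and lung libraries. The tissues were therefore not compared at equal depth.

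The circRNAs with the largest brain excess included some from genes of neurotransmitter release. Rims2 and Rims1 encode active-zone scaffolds that tether vesicles near calcium channels. The Rims2 circRNA at chromosome 15, 39398489 to 39448056 (mm9), measured 454.7 ± 66.9 in brain and 2.49 ± 4.37 elsewhere (log2 difference 7.67, limma adjusted p = 2.33e-09). The Rims1 circRNA at chromosome 1, 22336374 to 22369621 (mm9), measured 83.1 ± 11.1 in brain and 0 elsewhere, at least 299-fold (limma adjusted p = 2.23e-10). A second Rims2 and a second Rims1 circRNA were likewise at 0 outside brain, at least 124-fold and 165-fold lower. Unc79, a subunit of a sodium leak channel complex (5.74 log2 units), Anks1b, a postsynaptic density protein (6.17), and Ksr2, a kinase scaffold (5.59), were also among the largest, with limma adjusted p = 6.29e-10, 2.01e-09 and 1.37e-08. The presynaptic list as a whole was higher, with 56 of 75 circRNAs passing in the planned fit (57 adjusted over the list alone) and camera adjusted p = 7.94e-08 at the preset correlation.

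Postsynaptic hosts followed the same direction, with 36 of 44 circRNAs higher (37 and 1 lower adjusted over the list alone, camera adjusted p = 1.58e-05). Dlgap1, a scaffold that links PSD-95 to Shank proteins, rose by 4.21 log2 units (limma adjusted p = 2.33e-09), and the circRNA of the NMDA receptor subunit gene Grin2b was at 0 outside brain, at least 41.0-fold lower (limma adjusted p = 3.09e-09). Homer1 encodes a protein whose long form cross-links metabotropic receptors to the density. Its circRNA at chromosome 13, 94111711 to 94126034 (mm9), gave 54.9 ± 17.9 in brain and 4.69 ± 5.79 elsewhere (3.81 log2 units, limma adjusted p = 9.30e-07). That call was lost when circRNA totals were equalised (adjusted p = 0.0563). Ion channel hosts were higher for 27 of 36 circRNAs (27 adjusted over the list alone, camera adjusted p = 3.36e-05), among them the calcium channel gene Cacna1a (3.56 log2 units, limma adjusted p = 8.69e-09) and 2 circRNAs of the calcium release channel Ryr2 (3.43 and 3.32, limma adjusted p = 1.94e-06 and 3.31e-07). Ryr2 is also the main release channel of heart muscle. Circular forms of genes for splicing and RNA-binding proteins were higher for 14 of 24 (14 adjusted over the list alone, camera adjusted p = 0.0254, and adjusted p = 0.0501 with an estimated correlation). Among them the neuronal RNA-binding protein gene Elavl2 stood at 11.1 in brain and 0 elsewhere, at least 40.0-fold (limma adjusted p = 3.91e-09). All 5 circRNAs of nuclear-retained transcripts passed (camera adjusted p = 0.0189, and adjusted p = 0.110 with an estimated correlation), led by Rmst, a long noncoding RNA of neural progenitors (4.28 log2 units, limma adjusted p = 6.07e-07). The presynaptic, postsynaptic, ion channel and heart calls held with an estimated correlation (camera adjusted p = 0.00361, 0.0222, 0.00986 and 0.00221). Over circRNAs with at least 20 reads, the presynaptic (13 of 16 higher, camera adjusted p = 0.00782), postsynaptic (5 of 6, 0.0379), ion channel (6 of 6, 0.0379) and heart lists passed, and splicing (7 of 8) stopped at adjusted p = 0.0577. With an estimated correlation and that floor, the postsynaptic and ion channel calls were lost (adjusted p = 0.0819 each) while the presynaptic and heart calls stood at adjusted p = 0.0428.

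Some hosts outside the synaptic lists were as enriched. Tulp4 had an abundant circRNA outside brain too (29.1 ± 15.6) and rose by 3.80 log2 units to 418.9 ± 246 in brain (limma adjusted p = 1.72e-07). Circular RNA of the kinase genes Hipk3 (123 ± 7.22 against 6.54 ± 5.25, 4.27 log2 units, limma adjusted p = 5.88e-08) and Mapk4 (41.5 ± 14.0 against 0, at least 149-fold; limma adjusted p = 3.88e-10) rose. So did that of the actin-binding ubiquitin ligase adaptor gene Klhl2 (4.00, limma adjusted p = 1.40e-07) and Rtn4, which encodes the myelin inhibitor Nogo (2.99, limma adjusted p = 2.69e-06). Zfp609 rose by 3.14 (limma adjusted p = 4.82e-05), but not after scaling to equal medians (adjusted p = 0.111) or totals (adjusted p = 0.450). CircRNAs of Gabra4, Grm5, Erc2, Cacna1b and Kcnh1 were seen only in brain, with fewer than 20 reads each. The GABA synapse list counted 12 of 18 circRNAs higher (13 adjusted over the list alone, camera adjusted p = 0.0536), neuron 4 of 7 (0.317), dendritic mRNA 6 of 8 (0.185) and activity-regulated hosts 2 of 6, whose median was 0.17 while camera pointed down (adjusted p = 0.324).

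CircRNAs lower in brain included some of heart and lung genes. Heart hosts went down as a list (8 of 18 lower and 3 higher, 9 lower adjusted over the list alone, camera adjusted p = 2.18e-07). With at least 20 reads its median was -1.14 and its mean 0.36, because Ryr2 pulled the other way. Ttn, the giant spring protein of the sarcomere, had a circRNA at chromosome 2, 76695961 to 76719896 (mm9), at 0 in brain and 53.0 ± 94.2 elsewhere, at least 33.8-fold lower (-2.33 log2 units, limma adjusted p = 2.47e-06). EdgeR gave a larger difference without a call (-3.75, adjusted p = 1). Rtkn2 of alveolar cells and Lamp3 of surfactant vesicles were at 0 in brain, at least 2.43-fold and 5.23-fold lower (-0.94 and -1.31 log2 units, limma adjusted p = 8.73e-04 and 0.00107). There too edgeR gave larger differences without a call (-1.66 and -2.53, adjusted p = 1 each). The folds of Ttn, Rtkn2 and Lamp3 divide an arithmetic mean by the floor, and a few high libraries can raise that mean. Their limma differences average log2 values with a pseudocount and are smaller, so fold and difference are unlike measures. In the planned fit lung hosts were lower for 3 of 4 circRNAs and testis hosts for 2 of 3, and none of 4 cell cycle hosts passed. Oligodendrocyte hosts had 1 of 1 higher, while the single astrocyte and endothelial circRNAs did not pass. No circRNA of a progenitor, microglia, liver or heat shock gene was tested. In heart, liver and lung the 14-week library had no Y-linked transcript (Eif2s3y and Ddx3y both at 0) while their 20-week libraries did, so age and probable sex were mixed in those tissues.

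The next question was whether circRNAs exceeded what their host genes would give, asked by limma on the log2 ratio of circRNA to host TPM. The planned fit called 1115 circRNAs higher relative to host and 1322 lower, of 5420. The split of 45.8% higher was set by the pseudocount, at 71.2% with one of 1/5 the size and 23.1% with one 5 times larger. Its lower count was 690 and 693 without 20-week brain replicates 1 and 2 and 718 without the 14-week brain library. With at least 20 reads, 334 were higher and 96 lower of 823. The latter counts were 169 and 50 without 20-week brain replicate 1, 215 and 50 without replicate 2, 228 and 40 without the 14-week brain library, and 320 and 60 without 14-week testis. The largest differences relative to host were those of the chromatin kinase Tlk1 (4.78 log2 units, limma adjusted p = 1.14e-07), the phosphatase Cdc14b (4.47, 1.02e-06), Hipk3 (4.18, 2.46e-07), the nuclear matrix protein Hnrnpu (3.87, 1.59e-05), Plekha5 (3.85, 1.37e-07) and the transcription factor Zbtb20 (3.72, 1.21e-06). Among fixed hosts, Rims2 (2.02, limma adjusted p = 2.78e-04) and Zfp609 (2.37, 6.34e-04) also exceeded their genes. Tulp4 (1.37, 0.00582) lost its call without 20-week brain replicate 1 (adjusted p = 0.0597) or replicate 2 (0.0709). Homer1 (0.51), Rmst (0.58), Mapk4 (0.64) and Rtn4 (-0.09) did not pass, so no excess over their genes was shown. Klhl2 (0.89, limma adjusted p = 0.0426) lost its call in 11 of 15 sets without 1 library (adjusted p up to 0.162). In the planned fit a pseudocount 5 times larger reversed the ratio of Klhl2 (-0.84, limma adjusted p = 4.25e-04). It also reversed those of Homer1 (-0.65), Rmst (-1.09) and Mapk4 (-1.52). The lower calls of Sv2b (-4.29), Rims1 (-3.47 and -3.06), Adcy1 (-2.93), Nlgn1 (-2.67), Elavl3 (-2.40) and Dlgap1 (-2.18) belong to genes nearly silent outside brain, where the circRNA had 0 or 1 reads, so the ratio there was set by the pseudocount. The Rims1 circRNA with most reads was also lower (-0.52, limma adjusted p = 0.0459), a call lost in 8 of 12 sets without 1 library (adjusted p up to 0.0866). In the planned fit its ratio reversed to 1.78 (limma adjusted p = 4.86e-05) with a pseudocount of 1/5 the size, so its direction was not settled.

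The developmental comparison asked which circRNAs separate the hippocampus of P30 from that of E18, across the weeks in which neurons leave the cycle, synapses form and myelin appears. Summed circRNA was 11159 ± 472 at E18, 12616 ± 543 at P1, 9672 ± 164 at P10 and 18098 ± 447 at P30 (n=2 each), and the number above 0 went from 6760 ± 641 at E18 to 9413.5 ± 82.7 at P30. These totals and numbers were not tested. The number above 0 depends on depth, and the E18 libraries held 21105 and 17355 circRNA reads against 30684 and 30150 at P30. In the planned limma fit, 890 circRNAs were higher and 205 lower at P30 of 14200, against 214 and 31 with edgeR. Without E18 replicate 1 or 2 the planned counts were 0 and 0 (unadjusted p counts 1585 and 506, then 1522 and 383), and without P30 replicate 1 or 2 they were 1 and 1 each time, where the lone sample left is assumed to vary like the other groups. Over the 1556 circRNAs with at least 20 reads, 411 were higher (303 host genes) and 89 lower (78 host genes), and edgeR gave 433 and 89. Those counts were 300 and 44 without E18 replicate 1, 281 and 41 without E18 replicate 2, 176 and 62 without P30 replicate 1, and 167 and 52 without P30 replicate 2. Part of the rise was the larger total at P30, since equal medians left 241 and 127 (65.5% of calls higher, against 82.2%) and equal totals left 203 and 153 (57.0%). The median difference of 0.62 moved to 0.22 and 0.05 under those scalings.

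Among the circRNAs that rose, those with the largest differences came from varied hosts. The Plekha5 circRNA at chromosome 6, 140492241 to 140517402 (mm9), went from 0 at E18 to 21.5 ± 6.69 at P30, at least 24.7-fold (limma adjusted p = 3.69e-06), and Fmn1, a formin of actin filaments, from 0 to 17.0, at least 19.5-fold (limma adjusted p = 3.69e-06). The diacylglycerol kinase Dgki (5.20 log2 units; limma adjusted p = 2.44e-06), the signalling gene Arhgap32 (5.09, 9.76e-07), the heparan sulfate enzyme Ndst3 (5.03, 6.91e-06) and Dlgap1 (4.96, 7.80e-06) rose most, each with both P30 libraries above both E18 libraries. Rims1 rose from 4.21 ± 2.87 to 44.9 ± 0.404 (limma adjusted p = 2.44e-07), Homer1 from 4.99 ± 0.889 to 23.8 ± 1.64 (2.14 log2 units; 1.09e-04), Klhl2 by 3.25 (6.15e-06) and the metabotropic glutamate receptor gene Grm5 by 2.76 (2.40e-05). Hipk3 (1.13, limma adjusted p = 6.58e-04) and Mapk4 (1.08, 0.00478) rose less and did not pass after scaling to equal medians (adjusted p = 0.0805 and 0.145) or totals (0.170 and 0.305), nor without the P10 and P30 second libraries (limma adjusted p = 0.0541 and 0.0525). Rims2 (0.95, 0.00688) lost its call without E18 replicate 1 (adjusted p = 0.0527), without P30 replicate 2 (0.0630), without the P10 and P30 second libraries (0.0819) and under both scalings (0.247 and 0.489). Tulp4 (210.1 ± 26.7 at P30 and 210.4 ± 21.8 at E18), Zfp609 (-0.13) and Rmst (-0.78) did not pass. Relative to equal circRNA totals, limma called Tulp4 (-0.70, adjusted p = 0.00199), Zfp609 (-0.82, 0.0327) and Rmst (-1.46, 0.00123) lower at P30. Rmst was also lower with equal medians (-1.24, limma adjusted p = 0.00568), with edgeR (-0.83, adjusted p = 0.00926) and without E18 replicate 2 (-1.07, limma adjusted p = 0.0392).

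Fewer circRNAs fell. One circRNA of the noncoding locus 2610307P16Rik was at 10.4 ± 1.47 at E18 and 0 at P30, at least 11.7-fold lower (limma adjusted p = 1.13e-05). Aff3, a transcription elongation factor (-3.69 log2 units; limma adjusted p = 8.66e-05), Cbfb, partner of the Runx factors (-3.40, 1.44e-04), Rhobtb3 (-3.39, 2.50e-04) and Ezh2, the histone methyltransferase of progenitors (-3.26, 1.16e-04), fell with both libraries of each age apart. Erc2, an active-zone scaffold, had circRNAs going both ways. The one at chromosome 14, 28589345 to 28590428 (mm9), fell (-3.14, limma adjusted p = 1.83e-04, and 0.0511 without the P10 and P30 second libraries) while the one at 29116062 to 29130500 rose (1.25, 0.0414). That rise was lost without any of the E18 or P30 libraries (adjusted p = 0.0775 and 0.155 without E18 replicates 1 and 2, and 0.0522 and 0.29998 without P30 replicates 1 and 2). Rtn4 fell from 28.2 to 9.52 (-1.51, limma adjusted p = 1.91e-04).

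By host list, the planned fit moved presynaptic circRNAs up (25 higher and 2 lower of 241, 32 and 2 adjusted over the list alone, camera adjusted p = 0.0201), as well as postsynaptic (19 and 1 of 179, 20 and 1, camera adjusted p = 0.00772) and heart hosts (7 of 9, all Ryr2, camera adjusted p = 1.47e-05). The 7 heart circRNAs that passed came from the same host gene, also in the ion channel list, so they were not independent members. The presynaptic, postsynaptic and heart calls held with an estimated correlation (camera adjusted p = 0.0321 each). Ion channels (19 of 155 higher; 23 and 2 adjusted over the list alone, camera adjusted p = 0.0278, and adjusted p = 0.0826 with an estimated correlation) were lost. So were the downward calls of cell cycle hosts (none of 5 passing, 1 lower adjusted over the list alone, camera adjusted p = 0.00269, and adjusted p = 0.0826 with an estimated correlation) and nuclear-retained hosts (none of 15, camera adjusted p = 0.0278, and adjusted p = 0.118 with an estimated correlation). With at least 20 reads no list passed camera, the closest being postsynaptic (12 and 1 of 26, adjusted p = 0.0831), presynaptic (16 and 2 of 29, 0.112) and ion channels (7 and 2 of 17, 0.112). Lists without a camera call in the planned fit were GABA synapse (3 of 49, adjusted p = 0.167), activity-regulated (1 of 8, 0.237), progenitor (0 of 7, 0.378), neuron (6 and 2 of 35, 0.848), astrocyte (1 of 11, 4 adjusted over the list alone, 0.237), splicing (6 and 2 of 85, 0.798) and dendritic mRNA (2 of 22, 0.507).

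Genes were compared over the same ages to place these circRNAs in the cell changes of the tissue. Limma called 4552 genes higher and 4137 lower at P30 of 15444, with a median difference of 0.01 that equal medians moved to -0.12. Oligodendrocyte genes rose for 20 of 21 (camera adjusted p = 2.51e-13, and adjusted p = 0.0945 with an estimated correlation), as myelination starts after birth. Mobp went from 1.39 to 1990 ± 276 TPM (9.78 log2 units, limma adjusted p = 2.18e-07), Mbp from 10.4 to 3929 ± 210 TPM (8.42, 8.38e-08), with Mal (7.43), Mag (6.98) and Cnp (5.13) behind them. Astrocyte genes rose for 16 of 17 (camera adjusted p = 2.04e-09, and adjusted p = 0.101 with an estimated correlation), including the calcium-binding protein S100b (6.10), the receptor Ntsr2 (5.47) and the glutamate transporter Slc1a2 (3.57). Microglial genes rose for 16 of 16 (camera adjusted p = 1.26e-07, and adjusted p = 0.190 with an estimated correlation), with P2ry12 (2.71) and Trem2 (1.97). Cell cycle genes fell for 23 of 24 (camera adjusted p = 1.73e-14, and adjusted p = 0.0945 with an estimated correlation), with Cdk1 (-4.65), Ccnb1 (-4.38) and Cenpf (-4.03). Progenitor and immature neuron genes fell for 21 of 22 (camera adjusted p = 1.49e-13, and adjusted p = 0.0945 with an estimated correlation), with the microtubule protein Dcx (-4.68) and the intermediate progenitor factor Eomes (-4.25). The imprinted RNA H19 (-6.26), Cd24a (-5.77, from 1591 to 28.4 TPM), Gpc2 (-5.37), Igfbpl1 (-5.34) and the replication-dependent histones Hist1h3c (-5.09) and Hist1h2bl (-5.08) fell furthest.

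Synaptic genes rose beside these glial and cell cycle changes. Presynaptic genes were higher for 36 of 41 (camera adjusted p = 3.82e-13, and adjusted p = 0.138 with an estimated correlation), with the vesicle fission protein Dnm1 (4.50 log2 units), the SNARE Snap25 (from 246 to 2017 ± 239 TPM; 3.03) and synaptophysin Syp (2.94). Postsynaptic genes were higher for 37 of 42 and lower for 1 (38 and 1 adjusted over the list alone, camera adjusted p = 7.76e-11, and adjusted p = 0.0945 with an estimated correlation), with Camk2a (from 15.8 to 960 ± 192 TPM; 5.83), Cnksr2 (3.15) and Dlgap1 (2.57). GABA synapse genes rose for 23 of 24 (camera adjusted p = 8.04e-10, and adjusted p = 0.0945 with an estimated correlation), including the interneuron markers Pvalb (from 0.0588 to 98.9 TPM) and Vip (4.57). Ion channels rose for 27 of 31 with 1 lower (29 and 1 adjusted over the list alone, camera adjusted p = 7.40e-10, and adjusted p = 0.138 with an estimated correlation), with Kcna1 (3.91), Scn8a (3.54) and Kcna2 (3.18), channels of the axon and its initial segment. Neuron genes had 15 higher and 2 lower of 19 (camera adjusted p = 2.23e-06, and adjusted p = 0.138 with an estimated correlation), with Slc17a7 (4.48) and Thy1 (4.19). Dendritic mRNAs had 13 and 1 of 15 (camera adjusted p = 1.75e-06, and adjusted p = 0.0945 with an estimated correlation), with Ddn (6.16) and Nrgn (4.28). Activity-regulated genes had 23 and 6 of 37 (23 and 7 adjusted over the list alone, camera adjusted p = 3.40e-04, and adjusted p = 0.138 with an estimated correlation), with Arc (5.11), Ptgs2 (4.15) and Scg2 (3.29). All 12 of these gene list calls were lost with an estimated correlation.

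Other gene lists had no camera call at P30. Endothelium and blood genes went both ways (4 higher and 8 lower of 15, camera adjusted p = 0.352, median -0.73, mean 0.00), as the transporter Slco1a4 (4.84 log2 units) and Ly6c1 (2.41) rose and the globin gene Hba-a1 (-1.27) fell. Splicing and RNA-binding genes had 10 higher and 10 lower of 28 (camera adjusted p = 0.832, median -0.18, mean 0.14), with Mbnl2 (3.14), Rbfox3 (2.13) and the editing enzyme Adarb1 (2.05) up. Nuclear-retained RNAs (4 and 1 of 7, camera adjusted p = 0.152) included Snhg11 (3.84), Meg3 (1.70) and Rmst (-1.22), and heat shock genes (6 and 1 of 13, 0.262) included Hspa1b (2.03), Hspa1a (1.76) and Hspb1 (1.10). Heart genes (4 of 9, camera adjusted p = 0.110) included Ryr2 (4.15), Tnnt2 (1.46) and Myh7 (1.22), and lung genes (2 and 1 of 5, 0.617) included Sftpc (1.86). Of the liver genes tested 1 was higher and of the testis genes 3 were, among them Sycp3 (1.54) and Dazl (1.24). The choroid plexus transcript Ttr stood at 3429 TPM in P10 replicate 2 and 1286 TPM in P30 replicate 1 against 8.69 and 324 TPM in their partners, so libraries of the same age differed. P30 replicate 2 also carried 99520 TPM of 16 satellite-repeat models against 795 TPM in replicate 1, and without those models the gene counts were 4971 higher and 3838 lower. The largest of these models, Gm16869, reached 47796 TPM in that library.

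**Figure D2:**
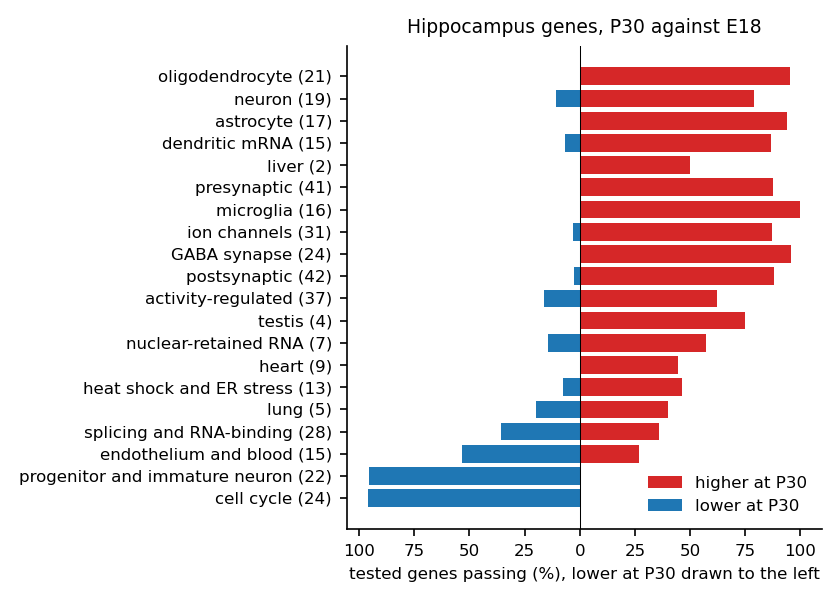
Percent of the genes of each fixed list that were higher (right) or lower (left) at P30 than at E18 in hippocampus, by limma. Myelin, glial and synaptic lists lie to the right, and cell cycle and progenitor lists to the left.

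Whether circRNAs moved beyond their genes was asked of the ratio of circRNA to host over the same ages. Across the 1525 circRNAs with at least 20 reads and a host value, which are not independent replicates, circRNA and host differences had a Pearson correlation of 0.565 (Spearman 0.531). Of the circRNAs that rose, 266 had a host gene that rose, 18 one that fell and 110 one that did not pass, and of those that fell 51 had a host that fell and 9 one that rose. Relative to host, limma called 254 higher and 382 lower of 13625 in the planned fit and 102 higher and 39 lower of 1525 with at least 20 reads. The latter counts were 69 and 12 without E18 replicate 1, 32 and 10 without E18 replicate 2, 13 and 15 without P30 replicate 1, and 5 and 3 without P30 replicate 2. Without the P10 and P30 second libraries they were 0 and 0 (unadjusted p counts 123 and 70), so none of the calls named below held there. The planned counts were 1 and 3 or 1 and 8 without E18 replicate 1 or 2, 14 and 23 or 16 and 30 without P30 replicate 1 or 2, and 115 and 178 or 97 and 150 without P10 replicate 1 or 2. The zinc finger gene Zfp101 (4.26 log2 units), the polarity kinase Brsk2 (4.12), Plekha5 (3.99) and the histone demethylase Kdm3a (3.92) exceeded their hosts most (limma adjusted p = 0.00201 each, both P30 above both E18 libraries). Of these, Zfp101 and Plekha5 were not among the circRNAs tested without the P10 and P30 second libraries. Arhgap32 (3.77, limma adjusted p = 0.00631) lost its call without P30 replicate 2 (0.0859). The early Erc2 circRNA fell relative to its gene (-4.21, limma adjusted p = 0.00303, and 0.0562 without P30 replicate 2), as did Anks1b (-3.27, 0.00389) and Aff3 (-3.03, 0.0103, and 0.0990 without P30 replicate 2). Homer1 (1.08, limma adjusted p = 0.203), Rims1 (0.69) and Rims2 (-0.30) did not pass, so no change beyond their genes was shown.

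**Figure D3:**
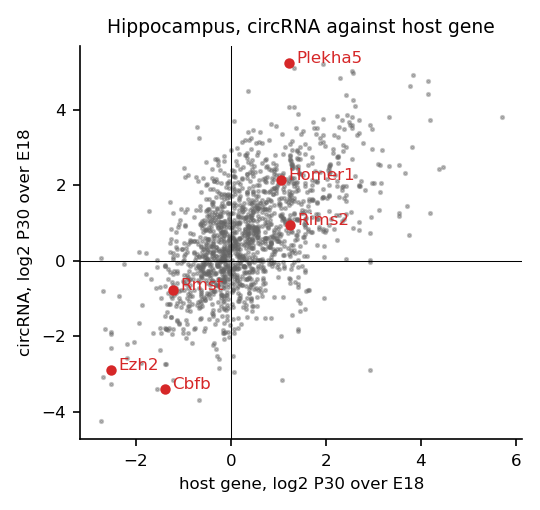
Log2 difference of each circRNA with at least 20 reads (vertical) against that of its host gene (horizontal), P30 minus E18. Points are circRNAs, the marked ones are the circRNAs with most reads of their host, and most points lie in the quadrants where both go the same way.

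Adjacent ages were compared in the planned fit. For P30 against E18 that fit found none of 82 simulated 4-fold circRNA changes, in data without the real stage differences. Its power on the real libraries is not known, so few calls do not place a change in time. For P1 against E18 limma passed 0 circRNAs higher and 0 lower (unadjusted p counts 788 and 517), for P10 against P1 0 and 1 (540 and 952), and for P30 against P10 618 and 115. Limma on genes, which had more power in simulated data, called 186 higher and 81 lower at P1, 2658 and 2779 at P10, and 2632 and 1929 at P30. Relative to host no step passed any circRNA in limma (0 and 0 at each; unadjusted p counts 638 and 318, 463 and 1259, and 1019 and 587). The Homer1 circRNA was at 8.06 and 5.87 in the P10 libraries and 24.9 and 22.6 at P30, and its gene at 116 and 125 TPM at P10 and 164 and 158 TPM at P30.

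Bicuculline was used to ask which transcripts respond to raised network activity, since it blocks GABA-A receptors and removes inhibition. Limma called 275 genes higher and 68 lower of 13341 (n=2 against 2). The counts were 31 and 2 without bicuculline replicate 1, 40 and 2 without bicuculline replicate 2, 234 and 37 without control replicate 1, and 370 and 228 without control replicate 2, where the lone sample left is assumed to vary like the other groups. Activity-regulated genes rose for 25 of 38 (33 adjusted over the list alone, camera adjusted p = 5.10e-38, and adjusted p = 0.227 with an estimated correlation). The transcription factors Fos (from 16.4 ± 7.19 to 870 ± 57.1 TPM; 5.71 log2 units, limma adjusted p = 0.00452), Npas4 (7.05, 0.00674), Fosb (4.97, 0.00321) and Atf3 (4.83, 0.00674) rose with the activin subunit Inhba (7.76, 0.00674), the growth factor Bdnf (3.72, 0.00309) and the kinase Plk2 (from 70.9 ± 2.14 to 907 ± 49.8 TPM; 3.66, 0.00165). The largest change was the protease inhibitor Serpinb2 (8.45, limma adjusted p = 0.00674), a target of nuclear calcium signalling. Also high were Fmo9p (6.77, 0.00508) and the matrix protein Cyr61 (5.79, 0.00795). Arc rose by 3.41 (limma adjusted p = 0.0266, and 0.0538 without bicuculline replicate 1).

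By unadjusted p limma counted 1239 genes higher and 1397 lower. Neurod6, a factor of pyramidal neurons, dropped from 208 ± 20.2 to 38.4 ± 0.936 TPM (-2.41 log2 units, limma adjusted p = 0.00482), and Rprml fell (-2.26, limma adjusted p = 0.0165, and 0.0664 without bicuculline replicate 2). Presynaptic genes had 2 higher and 2 lower of 40 (camera down, adjusted p = 0.0353, and adjusted p = 0.911 with an estimated correlation), with the priming factor Unc13b (1.65, limma adjusted p = 0.0141) and Ppfia2 (1.13, 0.0273) up and Erc2 (-0.95, 0.0463) down. Postsynaptic genes had 2 higher and 1 lower of 40 (camera adjusted p = 0.0536), with Homer1 (1.39, limma adjusted p = 0.0121) and Dlg1 (0.91, 0.0360) up and Baiap2 (-1.20, 0.0266) down. None of these 6 calls held without bicuculline replicate 1, where limma adjusted p was 0.153 for Unc13b, 0.148 for Ppfia2, 0.3002 for Erc2, 0.138 for Homer1, 0.289 for Dlg1 and 0.189 for Baiap2. Without bicuculline replicate 2 it was 0.102, 0.142, 0.142, 0.0838, 0.166 and 0.142 in the same order, and without control replicate 1 Erc2 (0.106) and Dlg1 (0.0716) were lost too. Nefl and Celf4, named with their lists here, were lost without bicuculline replicate 1 (0.228 and 0.3002), replicate 2 (0.0992 and 0.1702) and control replicate 1 (0.0525 and 0.0868). Heat shock and ER stress genes moved up (1 of 11, 5 adjusted over the list alone, camera adjusted p = 1.15e-04, and adjusted p = 0.405 with an estimated correlation). Only Atf3 passed, and the chaperone gene Hspa5 did not (0.79, limma adjusted p = 0.0584). Cell cycle genes moved up as a list with none of 24 passing (camera adjusted p = 0.0421, and adjusted p = 0.911 with an estimated correlation; Bub1 1.34, limma adjusted p = 0.0551). Ion channels had none of 31 (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0678), GABA synapse none of 24 (0.663) and neuron 1 of 17 (4 and 1 adjusted over the list alone, 0.797; Nefl 1.09). Dendritic mRNA had 2 of 15 (camera adjusted p = 0.593), progenitor 1 lower of 21 (0.252) and splicing 1 lower of 28 (0.291, Celf4 -0.81). Oligodendrocyte (none of 17, camera adjusted p = 0.873), astrocyte (none of 17, 0.415) and microglial genes (none of 11, 0.593) had no call. The myelin gene Mbp differed between replicate numbers more than between treatments, as it stood at 11.7 and 13.1 TPM in the first bicuculline and control cultures and at 89.8 and 105.6 TPM in the second.

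The same cultures were used to ask whether circRNAs respond to activity. The planned limma fit called 277 higher and 138 lower of 4120. All 415 had fewer than 20 reads, edgeR called 0 and 0 (unadjusted p counts 37 and 9), and simulated data without any change gave as many calls (622 of 5246). Leaving out any one of the 4 libraries also gave 0 and 0 (unadjusted p counts 69 and 284, 84 and 249, 461 and 19, and 484 and 14 without bicuculline 1 and 2 and control 1 and 2). With at least 20 reads, 1 of 326 rose and 0 fell (unadjusted p counts 8 and 4), with edgeR likewise 1 and 0 (14 and 5). Scaling to equal medians or totals gave 1 and 1 and moved the median from 0.22 to 0.03 and 0.01. The counts were 0 and 0 without bicuculline replicate 1 or 2 (unadjusted p counts 3 and 2, then 2 and 0), 2 and 1 without control replicate 1, and 1 and 0 without control replicate 2. The circRNA that rose came from Homer1, at chromosome 2, 42147315 to 42162026 (rn5), from 18.3 ± 6.84 to 95.7 ± 19.0 (2.36 log2 units, limma adjusted p = 3.46e-04), in 248 reads against 41. Over all circRNAs its limma adjusted p was 0.0831, edgeR gave 0.573, and without bicuculline replicate 1 or 2 the value over circRNAs with at least 20 reads was 0.964 or 0.238. The Homer1 gene rose from 63.3 ± 4.62 to 168 ± 10.5 TPM, so the circRNA relative to its gene (0.97) did not pass (limma adjusted p = 0.600). Relative to host limma passed 0 circRNAs higher and 0 lower of 3856 (unadjusted p counts 220 and 108) and 0 and 0 of 303 with at least 20 reads (21 and 5). In that smaller set the counts were 0 and 1 without bicuculline replicate 1, 1 and 0 without replicate 2 and 4 and 2 without control replicate 1. Dlgap1 (1.76, 13 against 2 reads) passed only in the planned fit (limma adjusted p = 0.0340), and Rtn4 (1.45), Rims1 (0.69), Klhl2 (0.08) and Hipk3 (-0.05) did not pass. No host list passed camera over all circRNAs (smallest adjusted p = 0.182, neuron) or with at least 20 reads (0.087 for presynaptic and for postsynaptic hosts, 0.428 for splicing). Across circRNAs, which are not independent replicates, circRNA and host differences correlated weakly (Pearson 0.144, n=303).

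**Figure D4:**
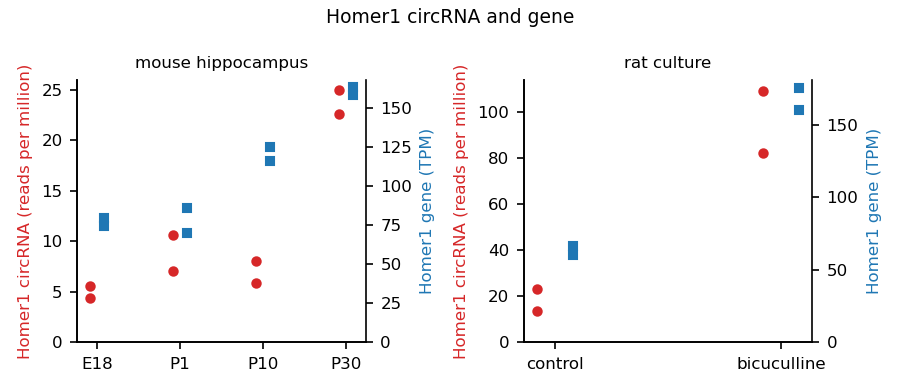
Homer1 circRNA (deposited RPM) and Homer1 gene (TPM) in each hippocampus library by age and in each rat culture by treatment. Points are libraries, and both measures are higher at P30 and with bicuculline.

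Synaptosomes were compared with their homogenate to ask which RNAs follow synaptic membranes, with 1 library each and therefore no test. Intervals for reads and floors cover counting error only, as PCR copies cannot be told apart without molecular identifiers. The circRNA total was 23898 in synaptosomes and 16367 in homogenate, a ratio of 1.46, and of 699 circRNAs with enough reads 80.0% were higher (median 0.51 log2 units), while the median gene was lower (-0.29). By host, presynaptic (19 of 22 higher, median 0.59, percentile 80.7 among matched random lists), postsynaptic (9 of 10, 0.72, percentile 80.3) and ion channel circRNAs (14 of 14, 0.55, percentile 66.8) moved with the other circRNAs and not beyond them. Splicing hosts stood at percentile 99.3 over all 87 circRNAs (0.82) and 59.6 over the 8 with enough reads. Over all their circRNAs, dendritic mRNA hosts (24 circRNAs, 0.55) stood at percentile 97.4 and nuclear-retained hosts (12 circRNAs, -0.39) at 3.77. Only 2 and 1 of these had enough reads, at 0.62 and 1.26, so the nuclear-retained one went the other way. Rims1 (ratio 2.85, 95% interval 2.21 to 3.70), Rmst (2.45), Rims2 (2.26, 1.65 to 3.12), Homer1 (1.85, 1.20 to 2.89), Dlgap1 (1.78) and Tulp4 (1.53, 1.27 to 1.85) were higher, and Klhl2 (1.10) and Rtn4 (1.08) nearly level. Among circRNAs with enough reads, Ano6 (19 against 1 reads) was highest, and Epb4.1l1 (139 against 26 reads, ratio 6.55, 4.29 to 10.4) was among the 5 highest. Zfp609 (3 against 23 reads, ratio 0.160, 0.0307 to 0.529) was lowest. Among genes, dendritic mRNAs (0.65, percentile 99.7), ion channels (0.53, percentile 100) and postsynaptic genes (0.18, percentile 99.4) were high, with Kif1a (from 278 to 3071 TPM), Eif4ebp2 (from 6.93 to 86.7 TPM) and Shank1 (from 34.4 to 316 TPM), all mRNAs of neuronal processes. Astrocyte (1.71, 17 of 17 genes) and microglial genes (1.69) stood at percentile 100 too, with the potassium channel Kcnj10 at 3.23, so RNA of glia was enriched in the fraction as well. Nuclear-retained RNAs (-2.54), endothelium and blood (-1.77; Hbb-b1 -4.42), activity-regulated genes (-1.004), heat shock genes (-0.92) and neuron genes (-0.92) were lowest. They were followed by lung (-0.77), progenitor (-0.62), splicing (-0.45), GABA synapse (-0.45), cell cycle (-0.34) and presynaptic genes (-0.29), with oligodendrocyte (-0.00) and heart genes (0.11) near 0.

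CA1 neuropil was set against CA1 somata to ask which circRNAs lie in the layer of dendrites and axons, again with 1 library each and no test. The circRNA total in neuropil was 2.05 times that of somata in mouse (26416 against 12909) and 2.00 times in rat (25907 against 12949.6). Of circRNAs with enough reads 97.1% of 279 in mouse and 95.3% of 316 in rat were higher in neuropil, with medians of 0.94 and 0.98 log2 units, while the median gene stood at 0.00 and 0.09. The shift was common to most circRNAs. In mouse, presynaptic (11 of 11, median 0.76, percentile 16.5), postsynaptic (6 of 6, 0.77, percentile 11.5) and ion channel hosts (7 of 7, 0.63, percentile 6.46) lay no higher than matched lists. Rat presynaptic hosts (9 of 9, 0.74, percentile 8.12) did the same. Rat postsynaptic hosts (11 of 11, 1.43, percentile 99.4) stood above matched lists among circRNAs with enough reads. Over all 155 their median was 1.09 (percentile 82.7). That is also the median of all 11579 circRNAs and the value of 1 read against 0, so it cannot decide whether postsynaptic hosts stood apart. Rat splicing hosts stood at percentile 55.3 with enough reads (5 of 5, 0.98) and 96.4 over all 57 (1.08). In mouse, Rmst (ratio 5.63, 95% interval 2.10 to 18.9), Erc2 (3.52, 1.53 to 9.05), Klhl2 (2.71), Rims1 (2.25, 1.49 to 3.44), Homer1 (1.91, 1.16 to 3.21), Rims2 (1.86), Hipk3 (1.79) and Tulp4 (1.62) were higher in neuropil. In rat, Hipk3 (3.56, 1.97 to 6.76), Zfp609 (3.02, 1.49 to 6.53), Rims1 (1.94), Homer1 (1.83, 1.39 to 2.42) and Klhl2 (1.67, 1.25 to 2.23) were higher and Mapk4 (1.06) level. Across 76 hosts shared by the species, 73 had circRNA higher in neuropil in both, as nearly all circRNAs were in each species. The size of the shift did not correlate (Pearson -0.05), and that of 7733 shared genes correlated at 0.734. Counting error of the circRNA ratios was wide, as for mouse Rims2 (54 against 34 reads, 95% interval 1.19 to 2.95). The lack of correlation therefore cannot show a difference between the species.

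Gene lists described the cells of the neuropil layer. Endothelium and blood (1.43 log2 units in mouse, 1.16 in rat), astrocyte (1.33 and 0.99), microglia (1.23 and 1.06) and oligodendrocyte genes (0.70 and 0.84) were higher in neuropil in both species at percentile 100 of matched lists. Dendritic mRNAs were also higher (0.37 and 0.63), and the vessel genes Acta2 (from 3.93 to 34.5 TPM) and Stab1 (2.72) led in mouse. Progenitor genes were higher too (0.42 and 1.05, percentiles 99.7 and 100). Cell cycle genes (0.40 and 0.69, percentiles 80.3 and 97.4) did not exceed matched lists in mouse. GABA synapse (-0.34 and -0.25, percentiles 0.18 and 3.03) and activity-regulated genes (-0.28 and -0.11, percentiles 0.01 and 3.57) were lower in neuropil, below percentile 5 of matched lists in both species. Neuron genes (-0.22 and -0.52, percentiles 10.1 and 0.01) were so in rat. Ion channel (-0.20 and -0.15, percentiles 6.28 and 6.82), heat shock (-0.20 and -0.13, percentiles 13.5 and 18.4), presynaptic (-0.16 and -0.16, percentiles 28.3 and 16.7) and postsynaptic genes (-0.19 and -0.05, percentiles 13.3 and 64.7) did not stand below the matched lists to that degree. Crhbp of interneurons stood at -1.54 in mouse. Nuclear-retained RNAs of mouse had a median of -0.37 (Malat1 0.05, Meg3 -0.13, Rmst 1.41), and lung genes 0.30.

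**Figure D5:**
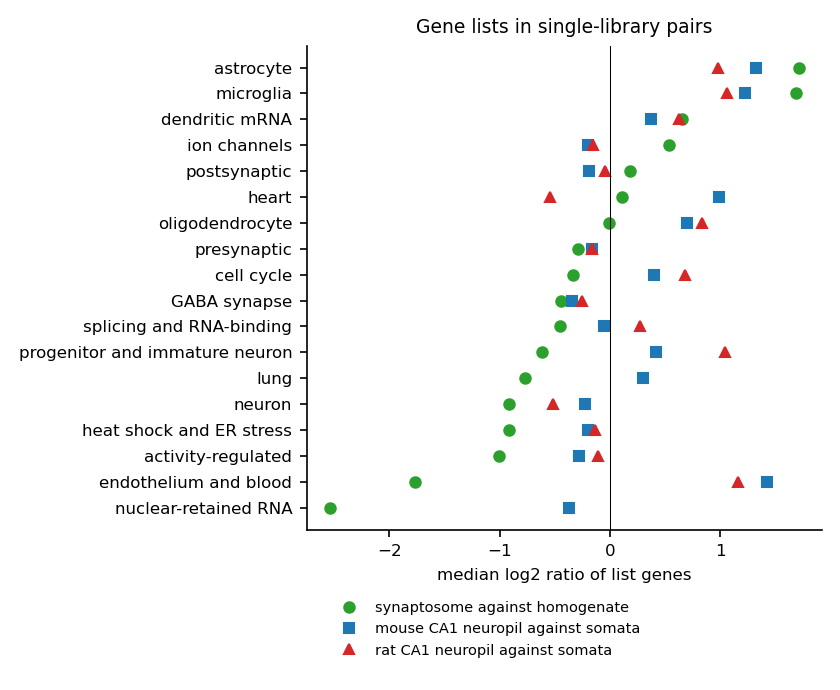
Median log2 ratio of the genes of each fixed list in synaptosomes against homogenate and in neuropil against somata of mouse and rat CA1, with 1 library per side. Glial and vascular lists lie right of 0 in neuropil, and nuclear-retained RNAs lie left of 0 in synaptosomes.

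The poly(A)-selected brain library asked whether the circRNA values depend on tailed RNA, because circRNAs carry no poly(A) tail. The circRNA total was 78.3 after selection for tails and 322 times higher in rRNA-depleted RNA of the same age, with 101 against 7445 circRNAs above 0 and 64 in both. Rims2 had 1 read against 324, Rims1 1 against 73, Tulp4 0 against 115 and Homer1 0 against 34. The untailed histone mRNAs behaved alike (27 genes, median -5.27 log2 units, against -0.26 for 10440 genes), as did the nuclear RNA Malat1 (from 7458 to 243 TPM; -4.94), which ends without a tail, while Snap25 (0.35), Eef1a1 (-0.75) and Camk2a (2.13) stayed in the library. No test was possible with 1 library each.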

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

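These results stood out after the values were seen; the tests on host levels, brain RNA, genomic DNA and nuclear dilution were written down before their own values were looked at, and the others after. In CA1, the medians of 2 gene lists had opposite signs in the mouse and rat pairs. Heart genes had a median log2 ratio of neuropil to somata of 0.99 in mouse (7 genes, percentile 99.5 of matched lists) and -0.54 in rat (8 genes, percentile 0.05). Only 1 heart gene reached a mean of 10 TPM in each species, at -0.20 in mouse and -0.52 in rat. Splicing and RNA-binding genes stood at -0.050 in mouse (percentile 72.8) and 0.27 in rat (percentile 99.8). Both splicing medians lay above the median of matched lists, so relative to those the direction was the same. Each value rests on 1 library per side, and the difference between species was not tested. No group had between 4 and 10 samples, so no single sample could be set apart from its group.

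Satellite-repeat gene models held 99520 TPM in P30 replicate 2 and 13096 TPM in P10 replicate 2, against 1030.4 TPM or less in the other 6 hippocampus libraries. Genomic DNA in the library was tested with olfactory and vomeronasal receptor models, which neurons of the hippocampus do not use. Their share above 0 was 60.5% in P30 replicate 2, 10.3 times the highest of the 6 other libraries, consistent with genomic DNA. For age, P30 replicate 1 held 0.772 times the level of the highest E18 library. The models were chosen for being higher in P30 replicate 2 than in P30 replicate 1, so this value cannot exclude age as a cause.

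The circRNA total of 14-week testis was 2.51 times the 20-week mean. A shift of all 14-week libraries was excluded, since the highest ratio among the other tissues was 1.19, and so were a few circRNAs, as the ratio without the 10 highest was 2.48. Brain RNA in the library was excluded, because neuron genes stood at a median of 0.00319 of their level in 14-week brain. Higher host genes were excluded too, with a median host log2 ratio of -0.10 against 1.14 for 213 circRNAs. Other differences of stage or cell make-up between the 14-week and 20-week animals were not tested, so the cause may be biological or technical.

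The circRNA total of CA1 neuropil was 2.05 times that of somata in mouse and 2.00 times in rat. A few circRNAs do not explain it, because the lower of the 2 ratios without the 10 highest was 1.999. Host gene levels do not either, with median log2 ratios of 0.21 in mouse and 0.10 in rat against 0.95 and 0.98 for the circRNAs. Dilution of the mouse somata library by nuclear RNA could not be decided, as the nuclear-retained list had a median of -0.37 over 7 genes that went both ways. Enrichment of circRNA in processes and a technical difference between the layers may both contribute, and 1 library per side cannot separate them.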

How the results depend on the processing

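Floors on reads, the length-matched lists, the blocked permutation, the fit without satellite models and the sets without named libraries were chosen after the results were seen; the other changes were set before. For counts and ratios of totals, moved means a change of more than 1.5 times. Medians of the single-library pairs were scored by an interval of the median, so smaller changes of these could count as moved. The results that answer a comparison were scored under changes set before the data were examined. Of these values 214 stayed alike, 102 moved, 2 reversed and 1 lost its call. Under added changes 101 stayed alike, 86 moved and 1 lost its call. Of values for named circRNAs and genes, 3868 stayed alike, 314 lost a call, 58 gained one, 63 moved and 6 reversed, and among the added changes 561 stayed alike, 44 lost a call, 10 gained one and 5 moved. Of list medians in the pairs 83 stayed alike, 17 moved and 4 reversed. Counts of circRNAs therefore depend on the read floor and the library set, while the totals kept their direction. Their exact permutation p was 0.0222 in 20-week libraries, 0.011 without any single brain library and 0.00275 without any single other library, in each case the smallest that the splits allow. Depth limits the circRNA tests, as most circRNAs have fewer than 20 reads. Values are given as higher and lower counts, and unless a reason is stated the cause was not tested.

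With fewer circRNAs tested, a floor of 10 reads gave 1266 and 135 in brain, 611 and 334 relative to host, 534 and 86 at P30, 101 and 48 relative to host, and 0 and 0 with bicuculline (unadjusted p counts 31 and 7 in limma). A floor of 20 gave 596 and 66, 334 and 96, 411 and 89, 102 and 39, and 1 and 0, and a floor of 50 gave 202 and 21, 133 and 20, 172 and 58, 78 and 26, and 1 and 0. With edgeR the planned circRNA counts were 2025 and 0 in brain (unadjusted p counts 2825 and 1), 214 and 31 at P30 and 0 and 0 with bicuculline (37 and 9), and with at least 20 reads 630 and 2, 433 and 89, and 1 and 0. No filter gave 31 lower in brain, 2627 and 7852 relative to host, 10 and 5 at P30, 776 and 1460 relative to host, 0 and 0 with bicuculline (unadjusted p counts 539 and 243), 1 and 10 relative to host and 72 and 6 genes. No trend gave 43 lower genes with bicuculline.

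Equal medians gave 1033 higher in brain, and with at least 20 reads 289 and 101 in brain, 241 higher at P30 and 1 lower with bicuculline. Equal totals gave 951 and 84 in brain and 0 and 0 with bicuculline (unadjusted p counts 513 and 242), and with at least 20 reads 219 higher in brain, 203 and 153 at P30 and 1 lower with bicuculline. A pseudocount 5 times larger gave 58 lower in brain, 2799 lower relative to host, 2106 and 3311 relative to host at P30, 36 and 81 with bicuculline, and circRNA medians of 0.28 and 0.29 in mouse and rat neuropil. It reversed the brain ratio to host of Homer1 (-0.65), Rmst (-1.09), Mapk4 (-1.52) and Klhl2 (-0.84). A pseudocount of 1/5 the size gave 396 lower in brain, 494 lower relative to host, 0 and 0 relative to host at P30 (unadjusted p counts 1198 and 612) and neuropil medians of 1.62 and 1.59, and reversed the ratio of Rims1 (1.78) and Erc2 (0.13). A gene pseudocount of 0.1 gave a synaptosome gene median of -0.33, and 5 gave -0.20 and a rat neuropil median of 0.065.

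Over pairs with a mean of at least 10 pseudocounts or 10 TPM, medians were -0.27 for synaptosome genes, 0.94 and 0.98 for mouse and rat neuropil circRNAs, and -0.082 and -0.015 for neuropil genes, which reversed. Centring on the median reversed synaptosome presynaptic circRNAs (-0.30), presynaptic genes (0.0086) and oligodendrocyte genes (0.29), and rat neuropil presynaptic circRNAs (-0.090). Length-matched lists placed synaptic hosts at percentile 95.8. The number of circRNAs at 10 pseudocounts or more was 1.27-fold (exact permutation, p = 0.0505). With an estimated correlation 3 circRNA lists and 0 gene lists passed camera at P30 and 0 gene lists with bicuculline, and with at least 20 reads 0 circRNA lists passed at P30.

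The 20-week libraries alone gave 1347 and 21 in brain and 494 and 340 relative to host, and without 14-week heart, liver and lung 97 were lower. Without the P10 and P30 second libraries, which hold most satellite models, P30 against E18 gave 0 and 0 circRNAs (unadjusted p counts 1252 and 564 in limma), 1 and 4 relative to host, 2541 lower genes, and with at least 20 reads 93 and 34 circRNAs and 0 and 0 relative to host (123 and 70). These sets have fewer samples. Leaving out each library gave 1545 to 2599 and 25 to 137 in brain, 690 to 1296 lower relative to host, 0 to 802 and 0 to 259 circRNAs at P30, 1 to 219 and 3 to 308 relative to host, 0 and 0 circRNAs with bicuculline, and 31 to 370 and 2 to 228 genes. With at least 20 reads the ranges were 385 to 590 and 21 to 65 in brain, 169 to 332 and 40 to 93 relative to host, 167 to 414 and 41 to 84 at P30, 5 to 150 and 3 to 54 relative to host, and 0 to 2 and 0 to 1 with bicuculline, 0 to 4 and 0 to 2 relative to host.

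The replicate number as a block gave 592 and 162 circRNAs at P30 and 1493 and 1805 genes with bicuculline, where the share of calls higher went from 80.2% to 45.3%. Other counts under the block were within 1.5 times, at 2676 and 117 in brain, 1109 and 1309 relative to host, 4902 and 4519 genes and 283 and 430 relative to host at P30, and 269 and 138 circRNAs with bicuculline. With the brain label moved only within the 3 blocks, the total (7.36-fold) and the number (3.65-fold) each gave p = 0.008 (exact permutation, the smallest of 125 splits). The labels do not say that a number marks a shared batch, so the block was not used elsewhere. Deviations from group means of same-numbered libraries correlated above 0.1 for 2 of 30 circRNA and 28 of 30 gene pairs of tissues (median 0.03 and 0.209), for 0 of 12 and 8 of 12 pairs of stages, and at 0.0579 for circRNAs and 0.588 for genes in the cultures. No paired analysis was possible because of 1 library per side for synaptosomes, neuropil and poly(A) RNA, and because synaptic hosts were counted over genes in the brain libraries alone.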

Other observations

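The circRNA at X:58436423 to 58439349 in mm9 lies at the known interval of the Cdr1 antisense circle, has no host symbol in the table and was matched by its coordinates after the values were seen. In brain it stood at 22.3 (19 reads) in the depleted 14-week library and at 14.8 and 11.5 at 20 weeks, and at 0 in all heart, liver, lung and testis libraries. In hippocampus it was at 0 and 1.87 at E18, 0 and 4.08 at P1, 2.30 and 2.93 at P10, and 8.11 and 9.16 at P30. In CA1 it stood at 11.9 in neuropil (11 reads) and 12.0 in somata (13 reads). It was at 8.24 in synaptosomes (15 reads) and 10.8 in homogenate (24 reads). These reads are too few to show a difference from other circRNAs. In the poly(A)-selected library it ranked 1 with 21 reads (12.9), while Rims2 had 1 read there. None of these differences was tested.

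The grouping of the 15 tissue libraries was tested against other splits of 3 and 12 by a limma fit with 2 groups and age, written down before the counts were seen. For circRNAs higher in brain the real split gave 2599 and was 1 of 100 as large, itself, the highest other being 1462 for the 20-week brain libraries and 14-week testis. For circRNAs lower in brain it gave 1, and 3 of 100 splits were as large, with 2 for the 20-week liver libraries and 20-week testis replicate 2 as the highest other. Relative to host the real split gave 192 higher and 462 lower and was 1 of 100 each time, the highest others being 11 and 79 for the heart libraries. In this fit of brain against all others as a single group, few circRNAs were lower in brain.

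In the circRNA table, replicate libraries differed by more than counting error in the 20-week testis pair (chi-square p = 0.00148) and in each hippocampal stage (p = 8.55e-05 at E18, 0.00133 at P1, 5.15e-07 at P10 and 6.65e-06 at P30) and culture group (1.47e-07 and 2.45e-15). For the other 20-week pairs the chi-square p over circRNAs was 0.0663 (brain), 0.0923 (heart), 0.288 (liver) and 0.815 (lung). Heart, liver and lung had only 32, 28 and 44 circRNAs, and heart had a chi-square of 1.35 per degree of freedom against 1.22 at E18, so no smaller excess was shown there. In the cultures Gfap stood at 3565 TPM with bicuculline and 3597 TPM in control for replicate 1, and at 4279 and 7176 TPM for replicate 2.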
